A study of Mus musculus with 13 samples.

How the data were processed

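RNA was measured in single CD45-positive cells sorted by FACS from retina and optic nerve of C57BL/6 mice, in 13 libraries made with 10x Chromium Next GEM Single Cell 3' v3.1 chemistry with dual index. Groups and replicate numbers were taken from the labels: 4 retina sham, 3 retina MB, 3 optic nerve sham and 3 optic nerve MB libraries, each pooled from 8 to 10 eyes. What MB stands for is not given in the sources used here. The deposited values are raw UMI counts per gene and cell barcode for 32285 genes, made by the authors with Cell Ranger 7.1.0 on genome build mm10 per the submitters' processing notes. The annotation release, the cell calling settings and the use of strand are not given in the sources used here. The libraries held 4464066 to 36060175 UMIs.

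Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial counts, which left 32206. Doublets were scored in each library against simulated doublets, and the highest scores were removed at a rate of 0.8% per 1000 cells, 792 cells or 2.46%. The 31414 cells used were clustered on 2000 variable genes, 30 principal components and 20 nearest neighbours by the Leiden method at resolution 1, without integration of libraries. Cells outside the microglia-like clusters were pooled and clustered a second time.

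Each cluster was named by fixed marker lists. It took the class with the highest mean log2 fold of its markers over the mean of clusters, with at least 3 detected markers and a score of at least 0.5. It stayed unnamed as mixed when another class reached its own best cluster's level divided by 3, or when the 10 leading genes by fold over clusters of other classes held more markers of another class. This naming rule is the 4th version. It was revised after marker levels per cluster, and from the 2nd version on cells per class and library, had been seen, and it was fixed before any differential test was run. The rule against markers of another class holds only with folds taken over clusters of other classes. With folds over all other cells, which is the strict naming used as an alternative, first-level clusters 3, 10 and 13 and second-level clusters 3 and 6 are refused. Cluster 13 held 787 microglia-like cells, 707 of them from retina MB. Second-level cluster 3 held 709 cells, 593 of them from retina MB, and cluster 6 held 531, 429 of them from retina MB.

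Counts were summed per class and library, for libraries with at least 20 cells of the class. Genes were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM normalization, filterByExpr and 1 fit over the 4 groups. The contrasts were MB minus sham in the retina, in the optic nerve and averaged over both, the difference of these effects, and optic nerve minus retina in sham eyes. Adjusted p-values follow Benjamini and Hochberg, with calls under 0.05. Class shares were compared by exact two-sided permutation within strata, over 700 arrangements for MB minus sham, adjusted over the classes. The arrangements take no account of the replicate numbers, which pair the libraries in gene expression as given below. The share difference between tissues was added later, by permuting treatment within each tissue, which takes no effect in either tissue as its null. Clustering used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9, and figures matplotlib 3.10.9.

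Gene lists, 30 with 760 symbols of which 23 stand in more than 1 list, were tested in microglia-like cells with camera at a preset correlation of 0.01. They cover microglial states, interferon, antigen presentation, cytokines, complement, cell cycle, stress, metabolism, lymphocyte activation, signs of RNA quality and markers of other cells. The ribosomal list also holds S6 kinase genes and Rps19bp1. Camera was repeated with the correlation estimated per list.

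The genes, lists, contrasts, filters, gene naming rule and alternatives were chosen before the data were examined, except for the naming of clusters and 3 alternatives to it. Genes are named by this rule: the 8 higher and 8 lower genes with the lowest p (5 and 5 outside microglia-like cells), with an adjusted p under 0.05, at least 10 CPM in the higher group and the same direction without any 1 library. Predicted genes, ribosomal, mitochondrial, hemoglobin and immunoglobulin genes and markers of other classes were passed over. The 4 members with the lowest p of each called list and 12 fixed genes were added, and where fewer than 5 genes passed, the 5 with the lowest p. Some genes that this rule takes are not reported here. Positions come from GENCODE M21.

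The replicate numbers were checked for pairing: after group means were removed, 18 of 18 pairs with the same number correlated above 0.1 (0.207 to 0.772 over 3838 genes), against -0.689 to 0.523 in the 36 other pairs, and 11 of 12 libraries were closest to 1 with their own number. A fit with the number as a block is therefore given beside results that it changes. No library was a copy of another of the same group, with a chi-square per degree of freedom of 7.16 to 49.9 between them. Libraries of different groups were not compared in this way.

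The test was tried on simulated data. The changed genes were drawn from those with a mean of at least 10 CPM, and no effect shared by libraries with the same number was simulated. The rates below therefore do not say how many changes were missed in the real data. In microglia-like cells edgeR recovered 90.3% of 2-fold and 100% of 4-fold changes in each tissue, with 5.47% false calls in the retina and 2.55% in the optic nerve; DESeq2 1.42.0 gave 12.8% and 13.0% false calls. In border macrophage-like cells edgeR recovered 26.7% of 2-fold and 83.7% of 4-fold changes, and in photoreceptor-like cells 27.1% and 93.3%.

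The alternatives were DESeq2, no filter on low counts, the replicate block, at least 50 cells per library, the groups of the contrast alone, doublets kept, a stricter cell filter of 500 genes and 5% mitochondrial counts, Leiden resolution 0.5 and 2, each library left out, edgeR on cell counts, shares of cells that are not microglia-like, camera with an estimated correlation and fry. Strict naming, log-score naming (the 3rd version of the rule) and first-level clusters alone were added after the data had been seen. Other classes were left out of the gene tests where a group lacked libraries with 20 cells, so that no class but microglia-like could be tested in the optic nerve.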

Results

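Single-cell RNA libraries were made from immune cells of the retina and the optic nerve of C57BL/6 mice, an inbred laboratory strain, to compare glaucomatous with control eyes. The cells were sorted by flow cytometry (FACS, sorting by fluorescent antibody) for CD45, a surface protein of blood-derived cells and microglia. The treated eyes were injected with a material that the labels call MB, and the control eyes were sham-injected. There were 4 retina sham, 3 retina MB, 3 optic nerve sham and 3 optic nerve MB libraries, each pooled from 8 to 10 eyes, so that p-values measure the spread between pooled libraries. Each library was a droplet library (10x Chromium), in which each RNA molecule carries a molecular identifier (UMI).

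The libraries held 615 to 5296 cells that passed the filters. The total UMI count was 18325922, 16166607, 29935582 and 36060175 in retina sham replicates 1 to 4, and 18028698, 12154476 and 33092606 in retina MB replicates 1 to 3. In the optic nerve it was 18525541, 4464066 and 17822273 in sham replicates 1 to 3, and 16825097, 10519994 and 21329698 in MB replicates 1 to 3. The median UMI count per cell was lowest in retina MB replicate 3, at 2063, next to 3786.5 and 6652 in retina MB replicates 1 and 2 and 5683 to 7567 in retina sham. Of 31414 cells used, 23917 were microglia-like, 973 photoreceptor-like, 537 natural killer cell-like, 468 border macrophage-like, 425 dendritic cell-like, 400 T cell-like, 190 B cell-like, 150 plasmacytoid dendritic cell-like and 85 neutrophil-like, and 4269 stayed unnamed. A first-level cluster of 731 cells, 693 of them from retina MB, was named monocyte. At the second clustering 407 of its cells stayed unnamed, 233 became dendritic cell-like, 67 plasmacytoid dendritic cell-like, 21 microglia-like and 3 border macrophage-like, so no monocyte-like class was compared. Photoreceptors lack CD45, the protein used for the sort.

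The first comparison asked which immune cell classes differ in abundance between MB and sham eyes. Natural killer cell-like cells, cytotoxic lymphocytes, rose from 0.205% ± 0.170 (SD, n = 4) to 4.12% ± 2.94 (SD, n = 3) of the sorted cells in the retina, and from 0.156% ± 0.0318 to 0.454% ± 0.116 (SD, n = 3 each) in the optic nerve. T cell-like cells made up 0.202% ± 0.140 (SD, n = 4) of retina sham and 3.97% ± 1.99 (SD, n = 3) of retina MB cells, and 0.589% ± 0.328 and 0.703% ± 0.130 (SD, n = 3 each) of optic nerve sham and MB cells. Microglia-like cells made up 85.0% ± 5.43 (SD, n = 4) of retina sham and 51.7% ± 21.7 (SD, n = 3) of retina MB cells, and 93.6% ± 2.84 and 93.6% ± 1.16 (SD, n = 3 each) of optic nerve sham and MB cells. The microglia-like share counts second-level cluster 3 (6.68% ± 7.45 of retina MB and 0.188% ± 0.117 of retina sham cells) and cluster 6 (3.53% ± 3.26 and 0.241% ± 0.115; SD, n = 3 and 4), the second led over all other cells by T cell genes. Cluster 6 held 429 retina MB cells, next to 400 T cell-like cells in all libraries, so the T cell-like share depends on how it is named. Of these 429 cells, 31, 30 and 368 came from retina MB replicates 1, 2 and 3. Their median UMI count was 16001, 20482 and 3483, next to 5651, 7385 and 6516 in microglia-like cells of first-level clusters. In cluster 3 the median was 792, 717 and 751.

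Averaged over both tissues, the share of natural killer cell-like cells was 2.11 percentage points higher in MB (exact permutation p = 0.00143, the smallest the 700 arrangements can give, adjusted p = 0.0129, two-sided). The arrangements ignore the replicate numbers, which pair libraries across groups and tissues in gene expression, so these p-values may overstate the evidence. The natural killer cell-like share was higher in 6 of 6 MB libraries than in every sham library of the same tissue. In the optic nerve this rests on few cells. The class was made up of second-level clusters 12 and 13, with 3 and 5 optic nerve sham cells and 1 and 25 optic nerve MB cells. The call held without any 1 library, with differences from 1.26 (without retina MB replicate 3) to 2.58 points. It held at 1.39 points with doublets kept and 1.18 under log-score naming. The T cell-like share was 1.94 points higher (exact p = 0.0114, adjusted p = 0.0429) and higher in 3 of 3 retina MB libraries than in every retina sham library. The microglia-like share fell by 16.7 points (exact p = 0.0143, adjusted p = 0.0429) and was lower in 3 of 3 retina MB libraries than in every retina sham library. Without second-level clusters 3 and 6 it fell by 21.9 points (exact p = 0.00714, adjusted p = 0.0321), and under strict naming by 27.6 points (exact p = 0.0186, adjusted p = 0.0495). The T cell-like call was lost without 10 of the 13 libraries in turn, with differences of 1.38 to 2.34 points, and the microglia-like call without 11 of 13, with differences from -20.2 to -10.4 points. Without optic nerve sham replicate 2 the number of classes called was 7, without optic nerve sham replicate 3 it was 2, without optic nerve MB replicate 1 it stayed at 3, and without each of the other 10 libraries it was 1. In the edgeR test of cell counts the microglia-like log2 change was -0.36, and with the replicate block -0.40, with adjusted p = 0.525 and 0.533; natural killer, T and dendritic cell-like cells were called there.

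The other classes did not pass the adjusted test. Dendritic cell-like cells made up 0.0381% ± 0.0106 (SD, n = 4) of retina sham and 3.16% ± 3.04 (SD, n = 3) of retina MB cells, a mean difference over both tissues of 1.52 points (exact permutation, adjusted p = 0.0579). The differences were 0.303 points for neutrophil-like and 0.564 points for plasmacytoid dendritic cell-like cells (adjusted p = 0.0514 for both), 0.676 points for border macrophage-like cells (adjusted p = 0.571), -0.267 points for B cell-like cells and 0.329 points for photoreceptor-like cells (adjusted p = 0.843 for both). No plasmacytoid dendritic cell-like cell was found among 11184 retina sham cells, which allows a share of up to 0.0268%, against 1.13% ± 1.35 (SD, n = 3) in retina MB, where 136 of 150 such cells came from replicate 3. Within the retina, the natural killer cell, T cell, dendritic cell, neutrophil, plasmacytoid dendritic cell and microglia-like differences each had exact p = 0.0286, the smallest the 35 arrangements can give for these 7 libraries. Within the optic nerve no exact p can fall below 0.10. Unnamed cells made up 25.9% ± 17.7 (SD, n = 3) of retina MB, 7.41% ± 3.43 (SD, n = 4) of retina sham, and 4.16% ± 0.821 and 3.66% ± 0.451 (SD, n = 3 each) of optic nerve MB and sham cells. The sort, the lower UMI count per cell in retina MB replicate 3 and the unnamed share can each set these shares.

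**Figure D1:**
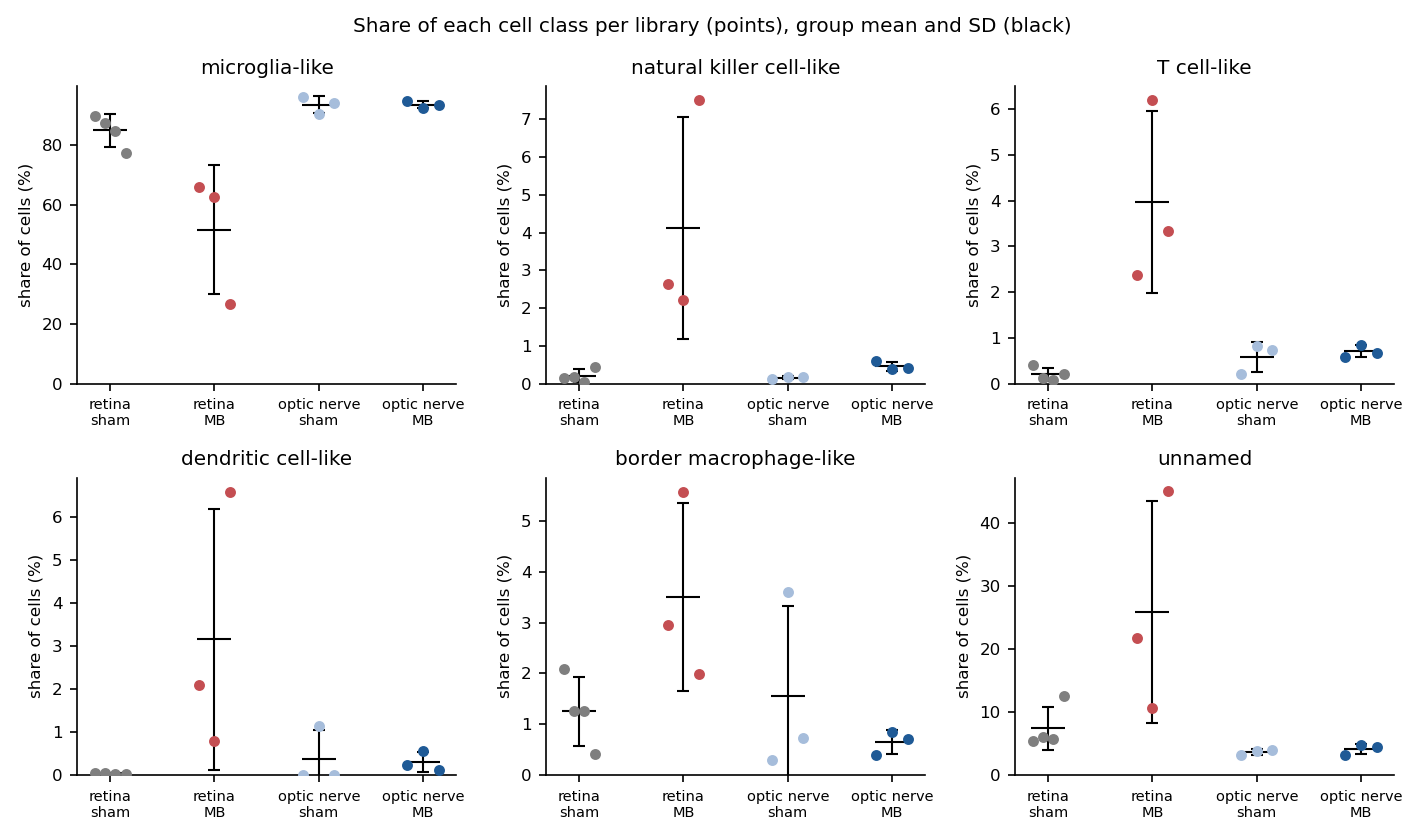
Share of all cells used, in percent, for 5 named classes and for unnamed cells, by group; points are libraries, and black marks give the group mean and SD (n = 4 for retina sham, n = 3 otherwise). Microglia-like cells made up 26.7% to 65.9% of retina MB cells and 77.5% to 90.0% of retina sham cells.

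The same shares were compared between tissues. Microglia-like cells were 25.2 percentage points higher in the optic nerve than in the retina, averaged over sham and MB eyes. They made up 93.6% of optic nerve and 85.0% of retina cells in sham eyes, and 93.6% and 51.7% in MB eyes. The difference was thus much larger in MB than in sham eyes. Photoreceptor-like cells differed by -5.12 points in the same average. They made up 4.81% ± 2.61 (SD, n = 4) of retina sham cells and 0 of 5525 optic nerve sham cells, which allows up to 0.0543%. Both averaged differences had exact permutation p = 0.00286 and adjusted p = 0.0129, again from arrangements that ignore the replicate numbers. All 6 optic nerve libraries lay above the retina libraries of the same treatment for microglia-like cells and below them for photoreceptor-like cells. The microglia-like call was lost at 17.3 points with doublets kept, 19.7 with the stricter cell filter, 13.6 at Leiden resolution 0.5 and 5.26 under strict naming, and in the edgeR test of cell counts, at log2 0.50 with and without the replicate block. The photoreceptor-like call was lost at -3.29 points with the stricter cell filter, and without optic nerve MB replicate 1, 2 or 3, with differences from -6.06 to -3.66 points over all libraries left out in turn. The number of classes called was 1 without each optic nerve MB library, 4 without retina sham replicate 1 or 2 and 5 without optic nerve sham replicate 2.

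The main gene comparison asked what changed in microglia-like cells of the MB retina. Genes of the disease-associated microglia programme, a set of lipid, lysosome and surface genes known from microglia in neurodegeneration, were higher. Apoe, a lipid carrier, rose from 819 ± 353 (SD, n = 4) to 8312.5 ± 3443 (SD, n = 3) CPM (counts scaled to the same library total), a log2 fold change of 3.34 (SE 0.36, edgeR adjusted p = 4.25e-05). Spp1, which encodes osteopontin, rose by 3.14 (SE 0.39, adjusted p = 0.000167) and Lgals3, which encodes galectin-3, by 3.54 (SE 0.33, adjusted p = 1.47e-05). Gpnmb, a transmembrane glycoprotein gene, rose by 4.35 (SE 0.60, adjusted p = 0.000354) and Cst7, a cysteine protease inhibitor gene, by 1.80 (SE 0.28, adjusted p = 0.000968). The complement gene C4b, whose reads can be shared with the near-identical C4a, rose from 3.14 ± 1.57 (SD, n = 4) to 60.6 ± 11.5 CPM (SD, n = 3), a log2 fold change of 4.28 (SE 0.39, adjusted p = 1.27e-05), and C3 by 2.09 (SE 0.22, adjusted p = 3.21e-05). The lowest p belonged to Cd244a, an immune receptor gene, at 12.3 ± 1.40 CPM in sham and 64.3 ± 6.76 CPM in MB (log2 fold change 2.40, SE 0.12, adjusted p = 2.1e-07). Each gene of this paragraph was higher in 3 of 3 MB libraries than in all 4 sham libraries. All 63 named genes called in the retina were without overlap between the groups, so this adds no support beyond the call. Each gene of this paragraph was also called with first-level clusters alone, the microglia-like cells left when those of the second clustering are taken out. These still hold cluster 13, with 707 of 787 cells from retina MB, which strict naming leaves out.

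In all, 818 of 15599 genes changed in the retina cells named microglia-like, 611 higher and 207 lower. With first-level clusters alone 285 genes changed, of which 277 were among the 818; under a strict reading of each cluster's leading genes 150 changed, of which 144 were among them. Of the 818 genes 657 were still tested in first-level clusters alone, 644 of them with the same direction and a median ratio of log2 changes of 0.858, and under strict naming 603, with 593 and 0.728. First-level clusters alone leave out 2 second-level clusters, which held 24.9%, 5.58% and 40.3% of the microglia-like cells of retina MB replicates 1, 2 and 3, against 0.220% to 0.844% in retina sham. Strict naming also leaves out first-level clusters 3, 10 and 13, and of the 787 cells of cluster 13, 707 came from retina MB. Over all other cells the 2 second-level clusters were led by Ms4a7, Apoe, Lyz2 and H2-Aa in the one and by the T cell genes Themis, Skap1, Ms4a4b, Trbc2 and Cd3g in the other. Markers of T cells moved with these genes: 21 of the 24 T cell markers tested were higher (24 adjusted over the list alone), with a median log2 fold change of 3.72, and the list was called (camera adjusted p = 1.84e-42; adjusted p = 0.0174 with an estimated correlation). In first-level clusters alone 10 T cell markers were tested, with a median of 0.78 and 2 of 10 called. The T cell list kept its camera call there and under strict naming. Of the 818 genes, 69 were markers of another cell class, against 12 of the 285 and 7 of the 150. The 818 genes and the T cell and lymphocyte lists are values of all cells named microglia-like, and whether microglia themselves changed was not settled for genes lost with first-level clusters alone. The microglia-like cells lay mostly in first-level clusters 1 (33.1%) and 2 (29.3%) in retina sham, and 13 (17.9%), 4 (17.5%) and 2 (12.2%) in retina MB.

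Among genes outside other classes' marker lists, Xdh, which encodes xanthine dehydrogenase, rose by 3.53 on the log2 scale (SE 0.21, adjusted p = 7.86e-07), Etl4 by 2.41, Adgb by 2.21, Cyp4f18 by 2.12, Mdfic by 1.63 and Trps1 by 1.54. Ccnd2, a cyclin gene, rose by 3.85 (SE 0.25, adjusted p = 1.54e-06), with 0.97 and adjusted p = 0.402 in first-level clusters alone. Lower genes with the lowest p were Kcnk12, a potassium channel gene, at -1.21 (SE 0.12, adjusted p = 2.24e-05), Upk1b at -1.96, Abcb4 at -0.85, Adgrl2 at -1.13, Nid2 at -1.30, Dlc1 at -0.90, Klhdc8b at -1.28 and Adamts16 at -1.19.

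By gene list, 14 of 37 disease-associated genes were higher and 4 lower (18 and 5 adjusted over the list alone; camera adjusted p = 5.34e-13; adjusted p = 0.0315 with an estimated correlation). The lower members were Lpl, which encodes lipoprotein lipase, at -0.92 (SE 0.15, edgeR adjusted p = 0.00147), Serpine2, Ccl6 and Cd9. Of 19 lipid storage and efflux genes 10 were higher and 1, Lpl, lower (11 and 1 adjusted over the list alone; camera adjusted p = 4.23e-15; adjusted p = 0.0174 with an estimated correlation), with Fabp5, a fatty acid binding protein gene, at 3.88 and Apoc2, an apolipoprotein gene, at 4.24. Of 40 type I interferon response genes 17 rose (26 adjusted over the list alone; camera adjusted p = 3.21e-21; adjusted p = 0.108 with an estimated correlation), among them Ifi207 at 1.53, Ifi206 at 1.33, Ifi204 at 0.98 and Slfn2 at 0.86. Ifi204, Ifi206 and Ifi207 are near-identical copies that can share reads, so each is uncertain on its own. Ifit3 had a log2 fold change of 0.46 (adjusted p = 0.387).

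Of 29 homeostatic microglia genes, expressed by microglia in healthy tissue, 9 fell (17 adjusted over the list alone; camera adjusted p = 5.69e-12; adjusted p = 0.0977 with an estimated correlation), among them Slc2a5 at -0.57, P2ry13 at -0.57, Arhgap5 at -0.44 and Gpr34 at -0.70. P2ry12, a purinergic receptor gene, was at 1558 ± 125 CPM (SD, n = 4) in sham and 1090 ± 160 CPM (SD, n = 3) in MB, a log2 fold change of -0.52 (SE 0.15, adjusted p = 0.0634), and Tmem119 was at -0.35 (SE 0.11, adjusted p = 0.0888). With the replicate number as a block the adjusted p was 0.000799 for P2ry12 and 0.0303 for Tmem119, and 1297 genes changed, 800 of them among the 818.

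Of 10 MHC class II presentation genes 5 rose (5 adjusted over the list alone; camera adjusted p = 2.27e-06; adjusted p = 0.0315 with an estimated correlation), with H2-Ab1 at 2.35 and Cd74, the invariant chain gene, at 2.13. In first-level clusters alone H2-Ab1 was at 0.85 (adjusted p = 0.0745) and Cd74 at 0.92 (0.223). Of 17 lymphocyte activation and cytotoxicity genes 13 rose (16 adjusted over the list alone; camera adjusted p = 8.31e-22; adjusted p = 0.0174 with an estimated correlation; median log2 fold change 2.52). Tox was at 5.12, Nkg7 at 5.16 and Cd69 at 2.41, while Gzmb, which encodes a cytotoxic granule protease, was at least 122-fold higher against a floor of 3 counts over the sham group. In first-level clusters alone the list had adjusted p = 8.99e-07, Tox was at 3.95 (adjusted p = 0.00683) and Cd69 at 1.39 (0.0709). Il1b, a cytokine gene, rose by 2.41 (SE 0.35, adjusted p = 0.000657), with 1.90 and adjusted p = 0.0781 under strict naming. Mki67, a proliferation gene, was at 0.46 (adjusted p = 0.713).

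The remaining called lists were lost with an estimated correlation. Complement had 3 of 15 genes higher (4 adjusted over the list alone; adjusted p = 0.00174; adjusted p = 0.16 with an estimated correlation). Glycolysis and hypoxia response had 4 of 26 (7 adjusted over the list alone; 0.00207; adjusted p = 0.128 with an estimated correlation). MHC class I presentation had 3 of 18 (4 adjusted over the list alone; 0.0115; adjusted p = 0.592 with an estimated correlation), where H2-Q6 and H2-Q7 can share reads. Signs of other cells and of RNA quality moved too. Border macrophage markers had 5 of 13 genes higher (5 adjusted over the list alone; 0.00128; adjusted p = 0.302 with an estimated correlation). Ribosomal protein and S6 kinase genes had 1 of 90 higher (0 adjusted over the list alone; 3.38e-05; adjusted p = 0.647 with an estimated correlation). Mitochondrially encoded genes had 0 of 13 called, with a median of 0.64 (0 adjusted over the list alone; 8.43e-05; adjusted p = 0.534 with an estimated correlation). Immediate early and heat shock genes had 2 of 28 lower (2 adjusted over the list alone; 0.000285; adjusted p = 0.592 with an estimated correlation).

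The lists not called in the retina were photoreceptor markers (camera adjusted p = 0.075), cell cycle (0.136), cholesterol synthesis and uptake (0.207), cytokines, chemokines and NF-kB targets (0.207), and endothelial genes (0.255). Others were phagocytosis and lysosome (0.292), fibroblast or mural (0.351), B cell (0.548), melanocyte or pigment epithelium (0.648), neutrophil (0.872), and nuclear oxidative phosphorylation, oligodendrocyte lineage, Muller glia or astrocyte and retinal neuron (0.82 each). The B cell list had a median of 0.32 and a mean of 0.97 but tested lower, the Muller glia list had a median of 0.07 and tested lower, and the retinal neuron list had a median of -0.03 and tested higher. With 1 oligodendrocyte gene at its bound that list's median was 0.06. The erythrocyte and surface epithelium lists had too few tested genes. With the replicate block, oxidative phosphorylation (0.00038), phagocytosis (0.011) and photoreceptor markers (0.00307) were also called higher. With first-level clusters alone cell cycle (0.0123) and phagocytosis genes (0.0168) were called higher, and MHC class I (0.102) and border macrophage genes (0.504) lost the call. Under strict naming cell cycle genes were called higher (7.45e-09) and oxidative phosphorylation (0.0248) and B cell genes (0.015) lower. MHC class I (0.407), glycolysis (0.0945), ribosomal (0.593) and border macrophage genes (0.413) lost the call there. Under log-score naming phagocytosis (7.88e-06) and endothelial genes (0.000678) were called higher.

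**Figure D2:**
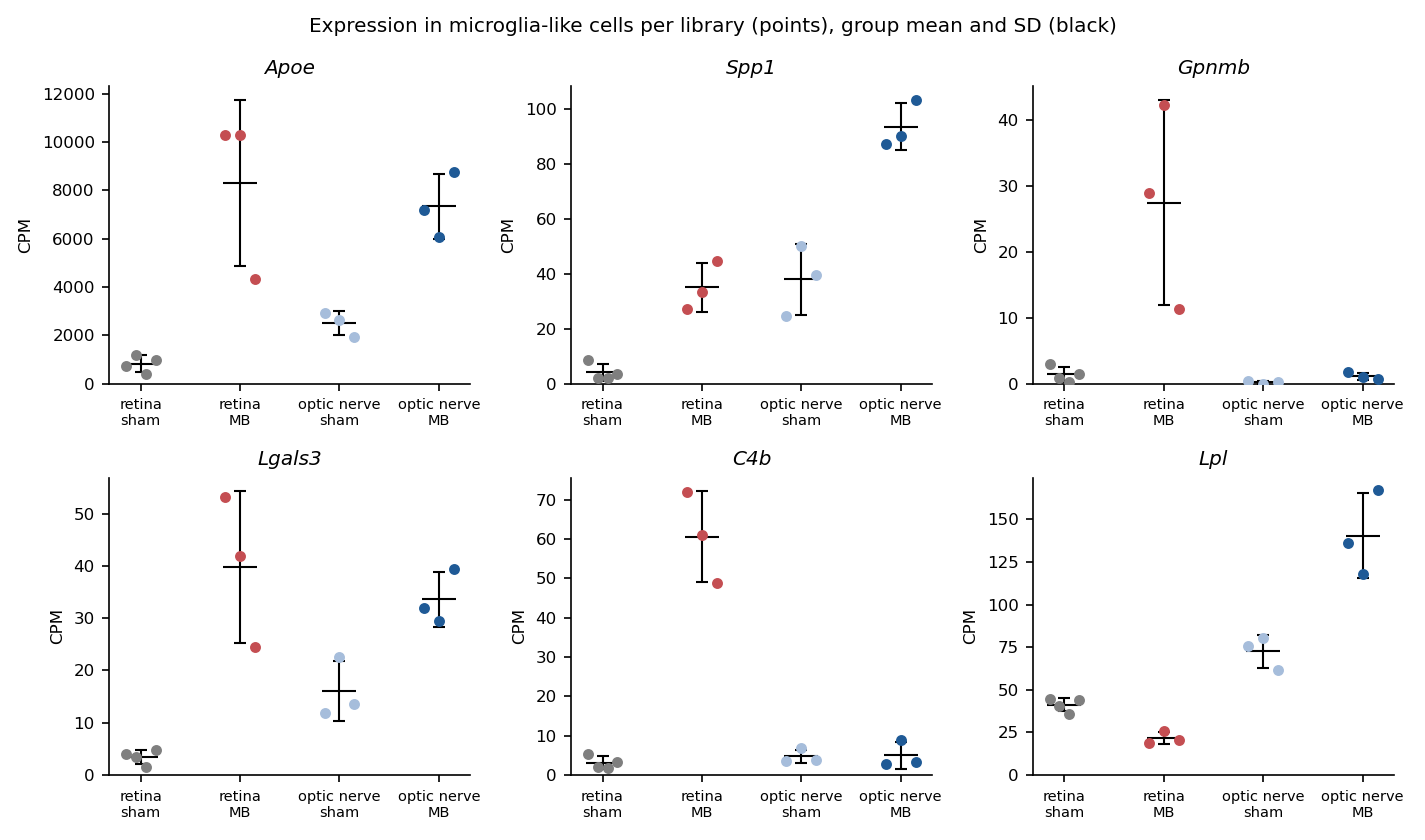
Expression of 6 genes in microglia-like cells, in CPM, by group; points are libraries, and black marks give the group mean and SD (n = 4 for retina sham, n = 3 otherwise). Apoe averaged 8312.5 CPM in retina MB and 819 CPM in retina sham, while Lpl averaged 21.9 and 41.4 CPM there and 140 and 72.6 CPM in optic nerve MB and sham.

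The same comparison was made in the optic nerve. Lipid storage and efflux genes were higher as a list in microglia-like cells of MB optic nerve, with a median log2 fold change of 1.02 over 19 genes (camera adjusted p = 1.03e-43; adjusted p = 0.000922 with an estimated correlation). Adjusted over the list alone 13 of them passed, although 0 did over all genes. The disease-associated list was higher as well, with 9 of 37 genes adjusted over the list alone (camera adjusted p = 3.84e-30; adjusted p = 0.00317 with an estimated correlation). It shares Apoe, Lpl, Fabp5, Ch25h, Lgals3 and Gpnmb with the lipid list, so the calls of these lists are not independent in any comparison. Cholesterol synthesis and uptake genes were lower as a list, with a median of -0.47, 0 of 19 genes above 0 and 0 adjusted over the list alone (camera adjusted p = 3.56e-20; adjusted p = 0.00317 with an estimated correlation).

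No single gene passed in edgeR (0 of 15599), where 340 genes had an unadjusted p under 0.05, and 754 with the replicate number as a block. Both counts are under the 5% that chance gives. The test may thus be conservative here, and 0 calls do not show that no gene changed. DESeq2 called 10, edgeR without the count filter 5, with the replicate block 7 and with the optic nerve groups alone 1. Without retina MB replicate 3 the count was 3, and without retina MB replicate 2 it was 1. As fewer than 5 genes passed, the 5 with the lowest p are given as values. Abcg1, a cholesterol exporter gene, was at 1.43 (SE 0.22, adjusted p = 0.104; 0.0198 with the block) and Lpl at 0.96 (SE 0.15, adjusted p = 0.104; 0.0285 with the block). Colec12, a border macrophage marker, was at 3.44 (adjusted p = 0.104; 0.0258 with the block), Igf1 at 2.81 (adjusted p = 0.136; 0.0198 with the block) and Siglecg at -1.34 (adjusted p = 0.194). Lpl averaged 72.6 ± 9.82 CPM in sham and 140 ± 24.9 CPM in MB (SD, n = 3 each). Apoe averaged 2502 ± 499 and 7336 ± 1353 CPM (SD, n = 3 each; log2 fold change 1.55, adjusted p = 0.924), and Spp1 37.9 ± 12.9 and 93.4 ± 8.48 CPM (SD, n = 3 each; 1.33, adjusted p = 1).

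Other lists called in the optic nerve were lost with an estimated correlation. Type I interferon (camera adjusted p = 1.45e-11; adjusted p = 0.409 with an estimated correlation), cell cycle (7.37e-07; 0.531), MHC class I (0.0259; 0.641) and endothelial genes (0.027; 0.388, and 0.0523 with the block) tested higher. Ribosomal (0.00298; 0.646), oligodendrocyte (0.00686; 0.517), oxidative phosphorylation (0.00686; 0.646), T cell (0.00926; 0.641), homeostatic (0.0105; 0.641), B cell (0.014; 0.393) and photoreceptor genes (0.0222; 0.646) tested lower, the last with a median of -0.31 with Rp1 at its bound. Leaving out 1 library turned the direction for homeostatic (0.778 without MB replicate 3), oxidative phosphorylation (0.795 without sham replicate 2) and ribosomal genes (0.919 without MB replicate 1), and without MB replicate 1 the lists called fell from 14 to 8. With the block, phagocytosis (0.0293) and glycolysis genes (0.0327) were also called higher and MHC class II genes (0.0264) lower. With first-level clusters alone T cell (0.26) and B cell genes (0.0552) lost the call, MHC class II genes (0.032) were called lower, and cytokine and glycolysis genes (0.0441 each) higher. Under strict naming homeostatic (0.125), endothelial (0.0728) and T cell genes (0.776) lost it, and MHC class II (0.0244) were called lower and lymphocyte activation genes (0.0372) higher. Under log-score naming MHC class II (0.00119) and border macrophage genes (0.0216) were called lower. The immediate early (median -0.04) and neutrophil lists (median -0.31) tested higher without a call. Most microglia-like cells lay in first-level clusters 3, 5 and 6 in both groups (33.7%, 21.05% and 17.3% in sham; 20.9%, 20.3% and 19.5% in MB). The mix of clusters still differed. Of all cells used, microglia-like cluster 10 made up 4.83% (3.23% to 6.2%) in sham and 11.5% (9.78% to 14.7%) in MB. How far the list changes follow this shift was not tested. Under strict naming, which leaves out clusters 3 and 10, lipid storage and disease-associated genes were still called higher (camera adjusted p = 1.6e-27 and 2.93e-19).

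Averaged over both tissues, 391 genes changed between MB and sham, 311 higher and 80 lower, against 166 with first-level clusters alone (162 shared with the 391), 73 under strict naming (73 shared) and 736 with the replicate block. Cd244a had the lowest p, at 1.28 (SE 0.09, adjusted p = 1.63e-05), followed among higher genes by Sh3pxd2b at 1.29, Cd72, a B cell co-receptor gene also expressed by microglia, at 1.0003, Mdfic at 1.03, Xdh at 1.87, Trps1 at 0.88, Chst2 at 1.83 and Etl4 at 1.32. The lower genes were Upk1b at -1.24, Kcnk12 at -0.65, Abcb4 at -0.50, Ctnnd2 at -0.89, Nid2 at -0.77, Fhit at -0.46, Gp9 at -0.91 and Sgip1 at -0.80. Apoe rose by 2.45 (SE 0.26, adjusted p = 0.000131), Lgals3 by 2.34, Spp1 by 2.24, Gpnmb by 3.20, Igf1, a growth factor gene, by 3.13, and Cst7 by 1.15. An averaged change can come from the retina alone. For Cd244a, Xdh, Lgals3, Upk1b, Kcnk12 and Abcb4 the MB effect differed between the tissues, as given below, so their averages describe neither tissue. Without optic nerve sham replicate 1 the count was 245.

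Lipid storage and efflux genes kept their call in the average with an estimated correlation, with 12 of 19 higher (13 adjusted over the list alone; adjusted p = 0.00215 with an estimated correlation). So did disease-associated microglia, 14 of 37 higher (18 higher and 2 lower adjusted over the list alone; 0.00533) and T cell markers, 8 of 24 (23 adjusted over the list alone; 0.0411). Lymphocyte activation kept it too, 4 of 17 (11 adjusted over the list alone; 0.0206), as did, lower, cholesterol synthesis with 0 of 19 genes called alone (0.0479). Over the T cell markers the median log2 fold change was 3.72 in the retina and -0.50 in the optic nerve, where the list tested lower. Over the lymphocyte activation genes it was 2.52 in the retina and -0.10 in the optic nerve. The averages of the T cell and lymphocyte lists thus come from the retina. Interferon (adjusted p = 0.0644 with an estimated correlation), homeostatic (0.0745), glycolysis (0.0745), MHC class II (0.0906), complement (0.171), border macrophage (0.237), MHC class I (0.407), mitochondrial (0.455), cell cycle (0.582), immediate early (0.593) and ribosomal genes (0.852) were called by camera and lost with it. With the block, cytokine (0.0453) and phagocytosis genes (0.00119) were called as well. With first-level clusters alone MHC class II (0.47), ribosomal (0.496) and border macrophage genes (0.149) lost the call, cytokine (0.0213), phagocytosis (0.00384) and endothelial genes (0.0406) were called higher and B cell genes (0.0118) lower. Under strict naming MHC class II (0.621), glycolysis (0.0519) and border macrophage genes (0.124) lost it. Ribosomal (0.0481), oxidative phosphorylation (0.00175) and B cell genes (0.0011) were called lower there, and under log-score naming phagocytosis (3.92e-06) and endothelial genes (0.000173) were called higher.

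The difference between the MB effects of the 2 tissues was tested directly. Lpl had effects of opposite sign: it fell from 41.4 ± 3.98 (SD, n = 4) to 21.9 ± 3.63 CPM (SD, n = 3) in the retina and averaged 72.6 and 140 CPM in optic nerve sham and MB. The difference of effects was 1.88 on the log2 scale (SE 0.21, edgeR adjusted p = 0.000522). Effects were lower in the optic nerve than in the retina for Cd244a (-2.23, SE 0.18, adjusted p = 4.83e-05), Xdh (-3.33, SE 0.32, adjusted p = 0.000199), Cyp4f18 (-2.10), Adgb (-2.07) and C4b (-4.16, SE 0.60, adjusted p = 0.00245). Higher effects in the optic nerve were found for Adgrl2 (1.24), Kcnk12 (1.12), Ptchd1 (1.07), Dlc1 (1.07) and Prkg1 (1.68). Of these, Adgrl2, Kcnk12 and Dlc1 fell in the retina, as given above. No gene was called in the optic nerve, so a higher effect does not by itself show a rise there. Adjusted p was 0.00231 for Adgrl2 and 0.00772 for Prkg1, a protein kinase gene. All genes of this paragraph were also called with first-level clusters alone.

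Of 15599 genes, 233 differed, 20 with a higher and 213 with a lower effect in the optic nerve. With first-level clusters alone 34 differed, all among the 233, under strict naming 3, under log-score naming 122, of which 91 were among them, with DESeq2 375, and with the replicate block 517, the 233 included. T cell markers moved with these genes, with 16 of 24 lower (20 adjusted over the list alone; camera adjusted p = 2.91e-49; adjusted p = 0.0112 with an estimated correlation), and 29 of the 233 were markers of another class. Of the 233, 153 were still tested in first-level clusters alone, 150 with the same direction and a median ratio of log2 changes of 0.81. There Ccnd2 (-4.53) was at -2.57 (adjusted p = 0.232), Ctsw (-5.29) at -3.43 (0.058), Gimap4 (-4.77) at -4.25 (0.773) and Adam19 (-4.54) at -1.16 (0.961). The difference for Apoe was -1.79 (adjusted p = 0.124; 0.0283 with the block) and for Spp1 -1.80 (adjusted p = 0.17), neither called without the block, and that for Lgals3 was -2.40 (adjusted p = 0.0148; -2.24 with 0.154 in first-level clusters alone). Without optic nerve MB replicate 1 the count was 154.

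Lymphocyte activation genes, 4 of 17 lower (13 adjusted over the list alone; adjusted p = 0.00799 with an estimated correlation), and MHC class II genes, 3 of 10 lower (5 adjusted over the list alone; 0.0265), also kept their call. Ribosomal (adjusted p = 0.733 with an estimated correlation), interferon (0.534), mitochondrial (0.733), cholesterol (0.382), complement (0.382) and photoreceptor genes (0.733) were called lower, and homeostatic (0.382) and immediate early genes (0.733) higher, and all lost the call with it. With the block, disease-associated (0.014), oxidative phosphorylation (5.19e-08) and glycolysis genes (0.00464) were called lower too. Under strict naming complement (0.309), lymphocyte activation (0.0666) and ribosomal genes (0.407) lost the call. Under log-score naming disease-associated (5.5e-09), lipid storage (0.000263), glycolysis (3.44e-05), oxidative phosphorylation (0.000824), phagocytosis (0.000388) and endothelial genes (0.0174) were called lower.

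Sham eyes were used to compare microglia-like cells of the optic nerve with those of the retina. Atp8b1, a phospholipid transporter gene, averaged 3.61 ± 0.651 CPM (SD, n = 4) in the retina and 23.4 ± 2.22 CPM (SD, n = 3) in the optic nerve, a log2 fold change of 2.71 (SE 0.16, edgeR adjusted p = 1.45e-06). C3 was higher in the optic nerve by 3.29 (SE 0.20, adjusted p = 1.45e-06), Etl4 by 2.67, Kynu, a tryptophan pathway enzyme gene, by 1.85, St8sia6 by 1.79, Cyp4f18 by 1.72, Mdfic by 1.43 and Ctse by 1.30. Lower in the optic nerve were Dlc1 at -1.75 (SE 0.12, adjusted p = 2.5e-06), P2rx1, a purinergic channel gene, at -2.44, Abcg3 at -2.42, Lilra5 at -2.05, Adam3 at -1.40, Peli1 at -0.97, Slc2a5, a fructose transporter gene, at -0.94 and Ggta1 at -0.78. Spp1 was higher by 3.22 (SE 0.39, adjusted p = 0.000316), Apoe by 1.61, Cst7 by 1.29 and Lgals3 by 2.16 (adjusted p = 0.00202; 0.659 under strict naming).

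In all 636 genes differed, 365 higher and 271 lower in the optic nerve, 598 with first-level clusters alone (567 shared), 489 under strict naming (409 shared) and 1491 with the block. RNA of each tissue's own cells moved with the comparison. Photoreceptor markers were lower, 8 of 26 (16 lower and 1 higher adjusted over the list alone), with a median of -2.48. Oligodendrocyte markers were higher, 5 of 11 (8 adjusted over the list alone), with a median of 2.03 and Ermn at least 48.5-fold higher against a floor of 3 counts over the group. The retinal neuron markers were also lower, 1 of 8 (3 adjusted over the list alone), with a median of -1.15 with 2 genes at their bounds and Snap25 at least 20.3-fold lower. These lists had adjusted p = 0.239, 0.0652 and 0.0937 with an estimated correlation. The count fell to 343 without optic nerve sham replicate 2, 365 without optic nerve sham replicate 1, 402 without retina sham replicate 3 and 412 without retina sham replicate 2.

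Glycolysis and hypoxia response genes were higher in the sham optic nerve, 8 of 26 (15 adjusted over the list alone; camera adjusted p = 2.33e-09; adjusted p = 0.0278 with an estimated correlation). Egln3 was at 1.09, Mif at 0.99, Hk2, a hexokinase gene, at 0.64 and Pkm, a pyruvate kinase gene, at 0.59. Called by camera but lost with an estimated correlation were disease-associated genes, 11 of 37 higher and 2, Cd9 and Ccl3, lower (adjusted p = 0.0652 with an estimated correlation). So were cholesterol (0.0652), lymphocyte activation (0.0652), lipid storage (0.228), T cell (0.275), MHC class I (0.34), ribosomal (0.34), mitochondrial (0.34), interferon (0.439) and oxidative phosphorylation genes (0.668), all higher. Homeostatic (0.263), B cell (0.275), immediate early (0.34), border macrophage (0.34) and cell cycle genes (0.5) were lower. With the block MHC class II (0.00115) and phagocytosis genes (0.00184) were called higher. Under strict naming disease-associated (0.174), cell cycle (0.55), oxidative phosphorylation (0.866), lipid storage (0.609), retinal neuron (0.329) and T cell genes (0.0843) lost the call, the last also with first-level clusters alone (0.156), and endothelial genes (0.0161) were called higher. The endothelial list had a median of -0.33 and tested higher, and the B cell list a mean of 0.03 and tested lower.

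**Figure D3:**
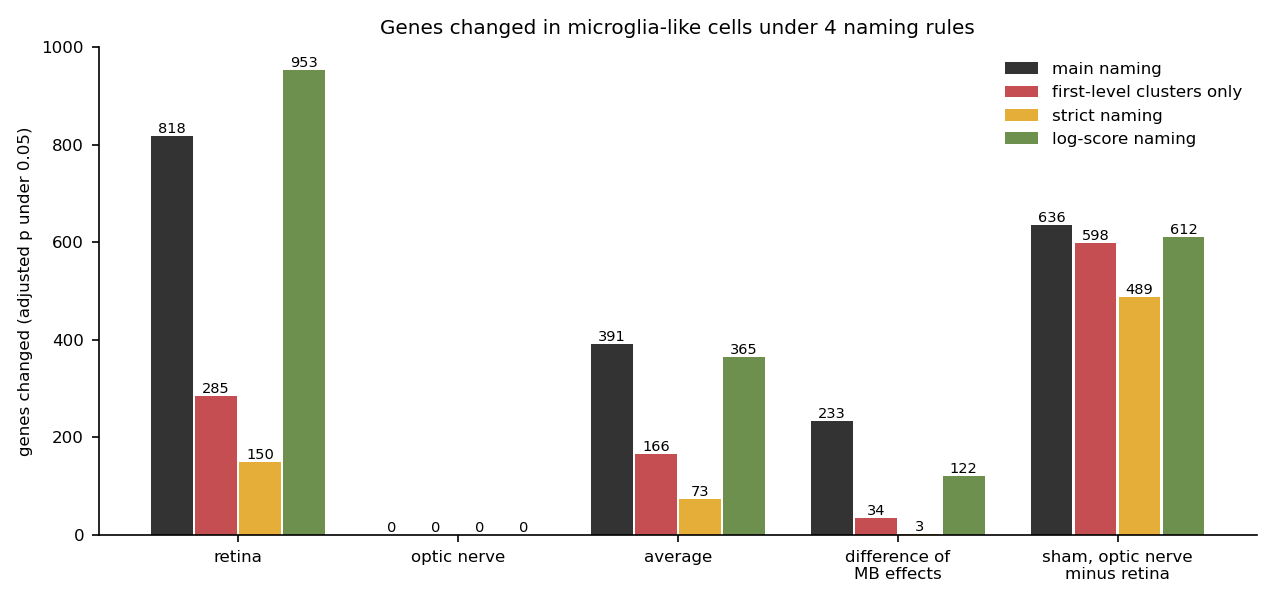
Number of genes changed in microglia-like cells (edgeR adjusted p under 0.05) for 5 contrasts under 4 rules for naming clusters; bars start at 0. In the retina the 4 rules gave 818, 285, 150 and 953 genes, and in the optic nerve 0 under each.

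Among other classes, border macrophage-like cells, macrophages of the tissue borders and vessels, and photoreceptor-like cells had enough cells for a test, and only in the retina. In border macrophage-like cells Arhgap24 rose from 73.4 ± 30.7 to 599 ± 124 CPM (SD, n = 3 each), a log2 fold change of 2.96 (SE 0.28, edgeR adjusted p = 3.79e-05). Acp5, which encodes a phosphatase of osteoclasts and macrophages, rose by 4.34 (SE 0.55, adjusted p = 0.000305) and Gdf3, a growth factor gene, by 4.15 (SE 0.54, adjusted p = 0.000355). Spon1 and Fgr, a kinase gene, were at least 35.9-fold and 18.3-fold higher against a floor of 3 counts over the sham group. Ppp1r9a was lower at -2.27, Pmp22 at -3.23, Dlc1 at -3.27, P3h2 at -2.98 and Magi1 at -2.52. Pmp22 turned to 0.36 with doublets kept and to 0.19 at Leiden resolution 2. Of 7164 genes 258 changed, 104 higher and 154 lower, with DESeq2 126, with the replicate block 454 and under strict naming 137. The cells came from 2 second-level clusters: cluster 9 held 127 retina sham and 141 retina MB cells, and cluster 20 held 6 and 115, so the mix of clusters differed between the groups. The count was 152 without retina sham replicate 2, 164 without retina MB replicate 1 and 171 without retina sham replicate 1, and retina sham replicate 4, with 12 such cells, was not used.

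In photoreceptor-like cells of the retina 0 genes passed in edgeR, with 229 at an unadjusted p under 0.05; DESeq2 called 0, edgeR without the count filter 91 and with the replicate block 31. The lowest p belonged to Fgf2os, at 12.996 ± 4.21 CPM (SD, n = 4) in sham and 48.0 ± 15.4 CPM (SD, n = 3) in MB. Its log2 fold change was 2.28 (SE 0.43, adjusted p = 0.385; 0.0126 with the block). It was followed by Fgf2, a growth factor gene, at 1.88 (adjusted p = 0.51; 0.00419 with the block). Fgf2os overlaps Fgf2 on the opposite strand, and whether strand was used in counting is not given in the sources used here, so neither is certain on its own. Lrrc2 was at 1.39 (0.00541 with the block), B3galt1 at 2.51 (2.15e-07) and H2-Ab1 at 2.81 (0.0279), each with adjusted p = 0.51 without it. Leaving out retina sham replicate 1 gave 2 genes and retina MB replicate 1 gave 1.

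In the mouse genome build mm10, with GENCODE M21 annotation and positions counted from 1, the main genes lie as follows. Apoe (ENSMUSG00000002985) is on chromosome 7 at 19696109 to 19699188 and Spp1 (ENSMUSG00000029304) on chromosome 5 at 104435118 to 104441050. Gpnmb (ENSMUSG00000029816) is on chromosome 6 at 49036546 to 49070929 and Lgals3 (ENSMUSG00000050335) on chromosome 14 at 47367751 to 47386160. Cst7 (ENSMUSG00000068129) is on chromosome 2 at 150570415 to 150578944 and C4b (ENSMUSG00000073418) on chromosome 17 at 34728380 to 34743882. Cd244a (ENSMUSG00000004709) is on chromosome 1 at 171559193 to 171609746 and Lpl (ENSMUSG00000015568) on chromosome 8 at 68880491 to 68907448. Abcg1 (ENSMUSG00000024030) is on chromosome 17 at 31057675 to 31117988 and Atp8b1 (ENSMUSG00000039529) on chromosome 18 at 64528967 to 64661267. Arhgap24 (ENSMUSG00000057315) and Fgf2 (ENSMUSG00000037225) are on chromosomes 5 at 102481391 to 102897937 and 3 at 37348346 to 37410108. Fgf2os (ENSMUSG00000054779) is on chromosome 3 at 37335332 to 37349740. Each span covers the whole gene, exons and introns together.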

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

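Tests of other immune RNA in the lost retina and interaction genes, of border macrophage RNA and of unnamed cells by monocyte markers were written before their results were seen. The tests without retina MB replicate 3, of other named immune RNA in the genes kept, of the replicate block, of the tissue difference in shares and of other splits were chosen only after the result was seen.

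Of 214 values tested in retina sham, the only group with 4 libraries, 15 had 1 library far from the other 3, and chance gives about 5%. Replicate 4 stood apart in the share of B cell-like cells (gap ratio 0.831; 3.099% against 0.0865% to 0.595%), the unnamed share (0.908; 12.5% against 5.35% to 6.01%), Pkm (0.871; 89.1 CPM against 73.6 to 75.6), Rpl10a (0.971; 437 against 309 to 313), and Olfml3 (0.848; 993 against 727 to 767). It also stood apart in H2-T23 (0.947; 110.0 against 79.5 to 81.1), Prkg1 (0.899; 25.7 against 35.9 to 37.0), St8sia6 (0.870; 32.5 against 47.8 to 50.1) and mt-Nd4l (0.917; 59.6 against 34.6 to 36.7). Replicate 3 stood apart in P2ry13 (0.871; 316 against 363 to 369), Smc4 (0.966; 34.7 against 26.2 to 26.5), and Stard4 (0.869; 3.90 against 4.55 to 4.65). It also stood apart in Lag3 (0.875; 60.0 against 68.4 to 69.6) and Mal (ratio 1; 0.0438 against 0, near the floor), and replicate 2 in Axl (0.917; 66.4 against 53.1 to 54.2). No cause was tested for these.

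A test of the difference itself set the MB effect in the optic nerve apart from that in the retina for 233 genes. Of the genes named, the effect was higher in the optic nerve for Lpl (1.88), Prkg1 (1.68), Upk1b (1.45), Adgrl2 (1.24), Kcnk12 (1.12), Ptchd1 (1.07), Dlc1 (1.07) and Abcb4 (0.72). It was lower for Cd244a (-2.23), Xdh (-3.33), Cyp4f18 (-2.10), Adgb (-2.07), C4b (-4.16), C3 (-1.87), Lgals3 (-2.40), Slfn2 (-1.06), Ifi207 (-1.06), H2-Ab1 (-2.43), Cd74 (-2.31), H2-Aa (-3.91) and Pdcd1 (-0.77). It was also lower for Ccnd2 (-4.53), Ctsw (-5.29), Gimap4 (-4.77), Adam19 (-4.54), Tox (-6.11), Nkg7 (-6.13), Gzmk (-5.19), Ms4a4b (-4.16), Skap1 (-4.16), Bcl11b (-4.55) and Cd3e (-5.34). Of the genes with a higher effect, Lpl, Upk1b, Adgrl2, Kcnk12, Dlc1 and Abcb4 were lower in MB than in sham retina. No gene was called in the optic nerve, so a higher effect does not by itself show a rise there.

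By list the camera test set the tissues apart for T cell markers (adjusted p = 2.91e-49), lymphocyte activation (4.89e-23), ribosomal (5.19e-08), interferon (7.67e-08), MHC class II (1.10e-07), mitochondrial (0.00112), cholesterol (0.00757), complement (0.00845) and photoreceptor genes (0.0107), all lower, and for homeostatic (4.88e-07) and immediate early genes (0.000635), both higher. With an estimated correlation only T cell markers (0.0112), lymphocyte activation (0.00799) and MHC class II (0.0265) kept the call. Ribosomal (0.733), interferon (0.534), mitochondrial (0.733), cholesterol (0.382), complement (0.382), photoreceptor (0.733), homeostatic (0.382) and immediate early genes (0.733) lost it. By share, permuting treatment within each tissue set the effects apart for microglia-like (33.3 percentage points), T cell-like (-3.65), natural killer cell-like (-3.62), dendritic cell-like (-3.19), border macrophage-like (-3.14), plasmacytoid dendritic cell-like (-1.13) and neutrophil-like cells (-0.607), each with adjusted p = 0.0386 by exact permutation. This test takes no effect in either tissue as its null, so an effect in the retina alone can give such a p. It also ignores the replicate numbers. The optic nerve held 0 plasmacytoid dendritic cell-like and 0 neutrophil-like cells, so for these 2 classes the value is the retina effect and no difference between the tissues was tested.

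The first pattern is the genes that are higher in retina microglia-like cells but are lost with first-level clusters alone. The 413 lost genes had a median log2 ratio of 2.16 (quartiles 1.15 to 3.20) in other immune classes over first-level microglia-like cells. The 198 kept genes had 0.18. This met the prediction for RNA or whole cells of other immune types in the second-level clusters. Genes were sorted into lost and kept by a test on the same first-level cells, so part of the contrast is built in. The ratios alone therefore do not decide for that cause. Without the second-level clusters 161 of the 413 were not tested. In the other 252 the median log2 fold change went from 1.70 (median SE 0.32) to 0.79 (quartiles 0.43 to 1.31, median SE 0.35). Their calls thus ended with smaller folds, not with folds of 0. Retina MB replicate 3 alone is argued against, since without it the T cell markers still had a median log2 fold change of 3.02, with 20 of 25 called. Whether microglia take up or express such RNA in MB eyes was not tested and stays open.

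The second pattern is the disease-associated and lipid genes that are higher in the retina. Border macrophage RNA is argued against only where it carries its usual markers. Of these, 6 implied a median share of 1.35% (quartiles 0.691 to 2.78), where 18 pattern genes would need 36.2%. The clusters were named by the same marker lists, so a low share was partly built in. In the same cells 5 of 13 border macrophage markers were called higher, and macrophages with few of these markers are not excluded. Retina MB replicate 3 alone is argued against too, as 17 of 19 pattern genes were called without it, and the same number with first-level clusters alone. RNA of unnamed cells cannot be told apart from a change in microglia: 5 monocyte markers implied 10.8% (quartiles 4.92 to 17.7), next to 17.8% for the 19 pattern genes, and the ranges meet. An effect of MB on microglia stays open and was not tested.

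The third pattern is the genes whose MB effect differs between tissues. For the 187 lower genes lost with first-level clusters alone, the median log2 ratio in other immune classes was 2.84 (quartiles 1.61 to 3.84). The 26 kept genes had 0.23. This met the prediction for other immune RNA, but the sorting on first-level cells builds in part of the contrast here too. Of the 187 lost genes, 80 were not tested without the second-level clusters. In the other 107 the median log2 value went from -2.49 to -1.23 (median SE 0.47 and 0.51). For the 26 kept, the share of a class's RNA implied by its own markers was compared with the median share that the kept genes would need. In first-level clusters the upper quartile of the implied share was at most 0.0105 of that need. For border macrophages, the class with that ratio, it was 0.591% next to 56.1%. This met the prediction against RNA of other named immune classes. The clusters were named by the same marker lists, so low shares were partly built in. The values argue only against RNA that carries these markers at the level of the named classes. Cells of those classes with few of the markers are not excluded. All 233 calls were kept with the replicate number as a block. The replicate numbers are nearly balanced over the groups, so the block could hardly change these effects (median ratio of log2 changes 0.998). Keeping the calls was therefore close to given and decides nothing on replicate batches. RNA of unnamed cells and a difference between the tissues in the response to MB stay open for the 34 genes called with and without those clusters.

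Other splits of the libraries into groups of the same sizes were counted, the real one included. In the retina 1 of 35 gave as many genes (818; highest other 46), between sham tissues 1 of 35 (636; highest other 4), in the average 1 of 100 (391; highest other 224) and in the difference of effects 3 of 100 (233; highest other 1223). These splits take no account of the replicate numbers, which pair the libraries. The split with 1223 genes put retina sham 3, MB 3 and sham 4 on one side, and such a number points to a structure of the libraries. The split with 778 kept the real retina labels.

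The real split parts every pair of libraries with the same number, so it was compared with the splits that do so too. For the retina (818; highest other 0) and the sham tissues (636; highest other 0) the 8 such splits are too few for a share under 0.05. For the average 1 of 64 gave as many (391, highest other 305), and with the replicate number as a block 2 of 32 (736, highest other 786). With the block chance is therefore not excluded. A split that keeps the real retina labels carries the retina effect into the average too, so these counts do not measure chance alone. For the difference of effects 6 of 64 gave as many (233; highest other 391), each with the real retina labels. Such splits carry the retina effect whatever the optic nerve labels are, so the splits decide nothing there. For the optic nerve (0 genes, 10 of 10 splits, highest other 6) and border macrophage-like cells (258, 1 of 10, highest other 0) the 10 splits are too few for a share under 0.05. For photoreceptor-like cells, with 0 genes, 35 of 35 splits gave as many and the highest other was 621. A count of 0 is reached by every split, so the splits decide nothing for the optic nerve or photoreceptor-like cells.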

How the results depend on the processing

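The 3 naming alternatives (strict, log-score and first-level clusters alone) were chosen only after the data had been seen; all other tests here were planned. Of values for named genes, 4294 kept their direction and side of the threshold under the alternatives other than leaving out a library, 246 lost the call, 171 gained it, 18 moved and 9 turned. Genes called in neither fit count as kept. Of the 4294, 405 came from the setting of at least 50 cells per library. In microglia-like cells that setting used the same 13 libraries as the main fit, so nothing could change there. For lists the counts were 450 kept, 135 lost and 7 turned, and for shares 141 kept, 14 lost, 9 gained and 10 moved. Where a value below changed, the cause was not tested, except that first-level and strict naming leave out cells. Optic nerve minus retina in sham eyes gave no result for classes other than microglia-like under any alternative. In simulated data 26.7% of 2-fold changes were recovered in border macrophage-like cells, among genes with a mean of at least 10 CPM.

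With the replicate number as a block, the genes changed were 1297 in the retina, 7 in the optic nerve, 736 in the average, 517 in the difference of effects, 1491 between sham tissues, 454 in border macrophage-like and 31 in photoreceptor-like cells. The list calls it gained or lost stand beside the results. Strict naming gave 150 genes in the retina, 73 in the average, 3 in the difference and 137 in border macrophage-like cells. First-level clusters alone gave 285, 166 and 34 in the first 3 of these, and log-score naming 122 in the difference. DESeq2 gave 10 in the optic nerve, 375 in the difference and 126 in border macrophage-like cells. No filter gave 5 in the optic nerve, 423 in border macrophage-like and 91 in photoreceptor-like cells, the groups alone 1 in the optic nerve, and in photoreceptor-like cells at least 50 cells per library gave 1 and the stricter cell filter 5.

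For MB minus sham shares, the number of classes called was 1 with shares of non-microglia-like cells, with the stricter cell filter and with log-score naming. The T cell-like difference lost its call at 4.90, 1.93 and 1.39 points under these 3, and the microglia-like one at -14.3 (stricter filter), -13.4 (log-score), and log2 -0.36 (edgeR) and -0.40 (edgeR with block). For optic nerve minus retina, the number of classes was 1 (non-microglia-like shares), 0 (stricter filter), 1 (resolution 0.5), 1 (strict naming), 4 (log-score), 4 (edgeR) and 5 (edgeR with block). The microglia-like difference lost its call at 17.3 (doublets kept), 19.7 (stricter filter), 13.6 (resolution 0.5), 5.26 (strict naming), and log2 0.50 (edgeR) and 0.50 (edgeR with block), and the photoreceptor-like one at -3.29 (stricter filter).

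The lists called numbered 14, 14, 16, 11 and 19 in the retina, optic nerve, average, difference and sham tissues. With an estimated correlation they were 5, 3, 5, 3 and 1, with fry 9, 3, 3 and 8 without the average, and with log-score naming 17 in the difference. Log-score naming also ended 6 list calls with the direction kept, which are not named above. Direction turned under strict naming for ribosomal genes in the retina (adjusted p = 0.593) and the average (0.0481), T cell markers in the optic nerve (0.776) and oxidative phosphorylation between sham tissues (0.866). It turned under log-score naming for border macrophage markers in the retina (0.698) and the average (0.116) and T cell markers between sham tissues (0.680). In the optic nerve it turned for homeostatic genes without MB replicate 3 (0.778), oxidative phosphorylation without sham replicate 2 (0.795) and ribosomal genes without MB replicate 1 (0.919). Leaving out other libraries gave adjusted p values down to 0.000116, 3.35e-06 and 8.83e-06 for these 3 lists.

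Single genes that turned were Dab2 in the retina at resolution 2 (-0.029) and in the average with the stricter filter (-0.20), resolution 2 (-0.23) and log-score naming (-0.073). Others were Lpl between sham tissues under strict naming (-0.011), Nkg7 (-1.37) and Skap1 (-0.11) between sham tissues under log-score naming, and Pmp22 in border macrophage-like cells with doublets kept (0.36) and at resolution 2 (0.19).

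Leaving out each library gave 596 to 931 genes in the retina, 0 to 3 in the optic nerve (3 without retina MB replicate 3, 1 without retina MB replicate 2), 245 (without optic nerve sham replicate 1) to 409 in the average. It gave 154 (without optic nerve MB replicate 1) to 284 in the difference and 343 (without optic nerve sham replicate 2) to 683 between sham tissues. The last was also 365, 402 and 412 without optic nerve sham replicate 1 and retina sham replicates 3 and 2. Border macrophage-like cells gave 152 to 239 and photoreceptor-like cells 0 to 2. The classes called ranged from 1 to 7 for MB minus sham and 1 to 5 for optic nerve minus retina, the T cell-like difference from 1.38 to 2.34, the microglia-like one from -20.2 to -10.4 and the photoreceptor-like tissue difference from -6.06 to -3.66. The lists called ranged from 8 (without optic nerve MB replicate 1) to 17 in the optic nerve.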

Other observations

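These values were looked at after the data had been seen, and no test was made of them. Second-level cluster 11, which stayed unnamed, held 300 cells, 277 of them from retina MB (160, 82 and 35 in replicates 1 to 3). It made up 4.22% ± 3.06 (SD, n = 3) of retina MB, 0.141% ± 0.105 (SD, n = 4) of retina sham, and 0.107% and 0.0511% of optic nerve MB and sham cells. Second-level cluster 2, also unnamed, held 1078 cells, 921 of them from retina MB replicate 3.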
